A study of Mus musculus with 12 samples.

How the data were processed

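RNA was measured in 12 libraries of embryonic day 9.5 mouse hearts, 3 libraries in each of 4 genotype groups. Per the labels, total RNA was purified with a column kit for small samples and sequenced on an Illumina instrument. The submitters' processing notes name STAR for alignment to the mm10 genome, HTSeq for counting and edgeR for the comparisons, without versions, gene annotation, strand or settings.

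The series deposited 4 tables of genes, each for 2 genotype groups, with 15211, 15005, 15172 and 15124 genes. The rule by which genes were left out of a table is not stated. The authors' expression values carry the unit signal. Their name calls them CPM, but the columns sum to 942334 to 1051801. All values (100.0%) are whole multiples of the value of 1 read in their column, within 0.01 read, so they are CPM on a library size scaled by 1 factor per library. The plan had assumed plain CPM. A library that stands in several tables has the same values in each, to within 4.4e-06 CPM, so the 4 tables were joined. Deposited fold changes and mean levels are in log2, and the deposited p-value and FDR columns are from the authors' own test. The deposited gene length was used only to remove a trend. Beyond these, 12 columns without headers, holding a few stray cells, were not used.

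Joined, the tables hold 15663 genes, of which 14810 are listed for all libraries. A gene absent from a table was not set to 0. Identifiers of 15522 genes (99.1%) were found in GENCODE M21 (GRCm38), from which positions and gene types were taken, and 795 symbols differed from that release. Reads in listed genes came to 25954539 to 42473118 per library, and 1 read was worth 0.0239 to 0.038 CPM. The 10 most abundant genes took 4.5 to 8.7% of reads. Where a group had no read of a gene, a floor of 3 reads over the group was used, which covers counting error alone. In all 12 pairs of replicates the libraries differed by more than sampling noise, with a mean chi-square per gene of 20.3 to 116.8 for genes with at least 20 reads and a lowest median of 4.71.

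Groups were compared with limma 3.58.1 (trend and robust) in R 4.3.3, on log2(CPM + 0.5) of genes with a mean of at least 1 CPM over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were Asb2 cKO, the group labelled Flna-deleted and the double mutant each against the control, and the double mutant against the Asb2 cKO. The double mutant against the group labelled Flna-deleted was added once the tables proved to share a scale. The interaction was fitted over all 12 libraries. The replicate numbers were not used as pairs. Across the 6 pairs of groups, libraries of the same number correlated at -0.46 to 0.43 after group means were removed, and in 0 of these pairs of groups did all 3 correlations exceed 0.1. The values were read with the package data.table, version 1.17.8, python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.

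A set of 28 gene lists of pathways and cell type markers was fixed before the data were examined, together with the comparisons, the alternative settings and the rule for named genes. Lists with at least 3 tested members, 27 of them, were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Members past the threshold were counted over all genes and adjusted over the list alone. The rule named Asb2 and Flna first. It then took, among genes past the threshold with at least 5 CPM in the higher group and no overlap between groups, the 8 largest rises and the 8 largest falls, leaving out clone and model names. For each list it took up to 3 members past the threshold with the smallest p, or up to 2 for markers of other cell types, and where fewer than 5 genes passed, the 5 genes with the smallest p. It named 79, 24, 81, 27 and 85 genes in the comparisons in the order above, of which the text gives a part. Some genes are not reported here.

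Overlaps of comparisons that share libraries were set against 50 simulations of unchanged groups, with noise drawn for each gene independently. Each comparison of 3 against 3 libraries was repeated over its 10 splits, and the interaction over 100 regroupings. Alternative settings chosen at that time were pseudocounts of 0.1 and 2, no filter and a filter of 5 CPM, rescaling by the median of ratios and without hemoglobin genes, limma without trend or robust, library weights, a block on the replicate number, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, a joint fit of the 4 groups and leaving out each library in turn. Added after the data were seen were Xist as a covariate, removal of trends over gene length and GC content (lowess span 0.3), and a joint fit without the 5 libraries with Xist at 1 CPM or more.

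The steps were tested on simulated counts in which 96 to 100 genes were changed 2-fold and 100 genes 4-fold per comparison. In the order above, limma recovered 64, 71.7, 68.8, 68.4 and 80.8% of the 2-fold changes and 86, 92, 86, 93 and 94% of the 4-fold changes. It called 162, 187, 162, 173 and 186 genes among 13986, 13930, 13953, 14009 and 13947 tested. Of these calls 12, 24, 10, 13 and 12 were false. In each comparison this was a larger share of the calls than the threshold on adjusted p aims at.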

Results

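Messenger RNA levels were measured by RNA sequencing of hearts dissected from mouse embryos at embryonic day 9.5, when the heart is a looped tube with forming chambers. All embryos carried a Cre recombinase driver labelled NkxCre, and 4 genotype groups of 3 libraries each gave 12 libraries. The control group had 1 floxed Asb2 allele. The Asb2 cKO group (cKO, conditional knockout) had both Asb2 alleles floxed. A group labelled as Flna-deleted had floxed Flna (labelled fl/fl) together with 1 floxed Asb2 allele. The double mutant group, labelled dcKO, had both genes floxed (labelled fl/fl for each). Libraries with the Flna label also differed from most others in sex-linked transcripts, which are given at the end. ASB2 is the subunit that gives a cullin-based ubiquitin ligase its substrates, among them the filamins, and filamin A, the product of Flna, crosslinks actin filaments. The design asks which transcripts change when Asb2 is deleted in the heart, and whether deletion of Flna alters those changes. The libraries held 25954539 to 42473118 reads in the listed genes, so that 1 read was worth 0.0239 to 0.038 CPM, the unit of read counts scaled by library size. Levels are given in CPM on the scaled library sizes of the deposited tables, as mean ± SD of the 3 libraries of a group. Fold changes are differences of log2(CPM + 0.5), which understates the change of low genes, with the standard error (SE) and Benjamini-Hochberg adjusted p of limma's moderated test. The labels do not say whether the 3 libraries of a group came from separate animals or pools, so p-values measure the spread between these libraries, part of which may be technical.

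The targeted genes were examined in every library first. Asb2 (ENSMUSG00000021200, chromosome 12, 103321142 to 103356001, minus strand, GRCm38/mm10) stood at 289, 183 and 218 CPM in the control libraries, 77.8, 163 and 115 CPM in the Asb2 cKO, 125, 113 and 197 CPM in the libraries labelled Flna-deleted, and 122, 121 and 153 CPM in the double mutant. It fell in the Asb2 cKO (log2 fold change -0.99, SE 0.26, adjusted p = 0.0248) and in the double mutant (log2 fold change -0.78, SE 0.17, adjusted p = 0.00724). The difference for the libraries labelled Flna-deleted did not pass (log2 fold change -0.68, SE 0.24, adjusted p = 0.334). The Asb2 call in the Asb2 cKO was lost without control library 1 (-0.82, adjusted p = 0.0589), without control library 3 (-1.02, adjusted p = 0.0569) and without Asb2 cKO library 3 (-1.002, adjusted p = 0.0668), within a range of adjusted p from 0.00128 to 0.107 over 21 alternatives. Flna (ENSMUSG00000031328, chromosome X, 74223461 to 74249820, minus strand) was not lower in the libraries labelled Flna-deleted. It stood at 490.3, 554 and 721 CPM in the control libraries, 1032, 869 and 725 CPM in the Asb2 cKO, 958, 1011 and 989.5 CPM in the libraries labelled Flna-deleted, and 1012, 1012 and 1146 CPM in the double mutant. Flna rose in the double mutant (log2 fold change 0.86, SE 0.15, adjusted p = 0.00255), and its value in the libraries labelled Flna-deleted was above the control without passing (log2 fold change 0.76, SE 0.14, adjusted p = 0.147). Its rise in the Asb2 cKO (log2 fold change 0.58, SE 0.18, adjusted p = 0.0464) was lost without control library 1 (0.45, adjusted p = 0.16) or 2 (0.54, adjusted p = 0.13) and without Asb2 cKO library 1 (0.45, adjusted p = 0.124) or 2 (0.57, adjusted p = 0.0827), within 0.00718 to 0.16 over 21 alternatives. These are counts over whole genes and over all cells of the dissected hearts. They do not show whether single exons were missing, or missing in part of the cells, so they do not refute the label. Every direction given here for the libraries labelled Flna-deleted rests on the label alone.

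**Figure D1:**
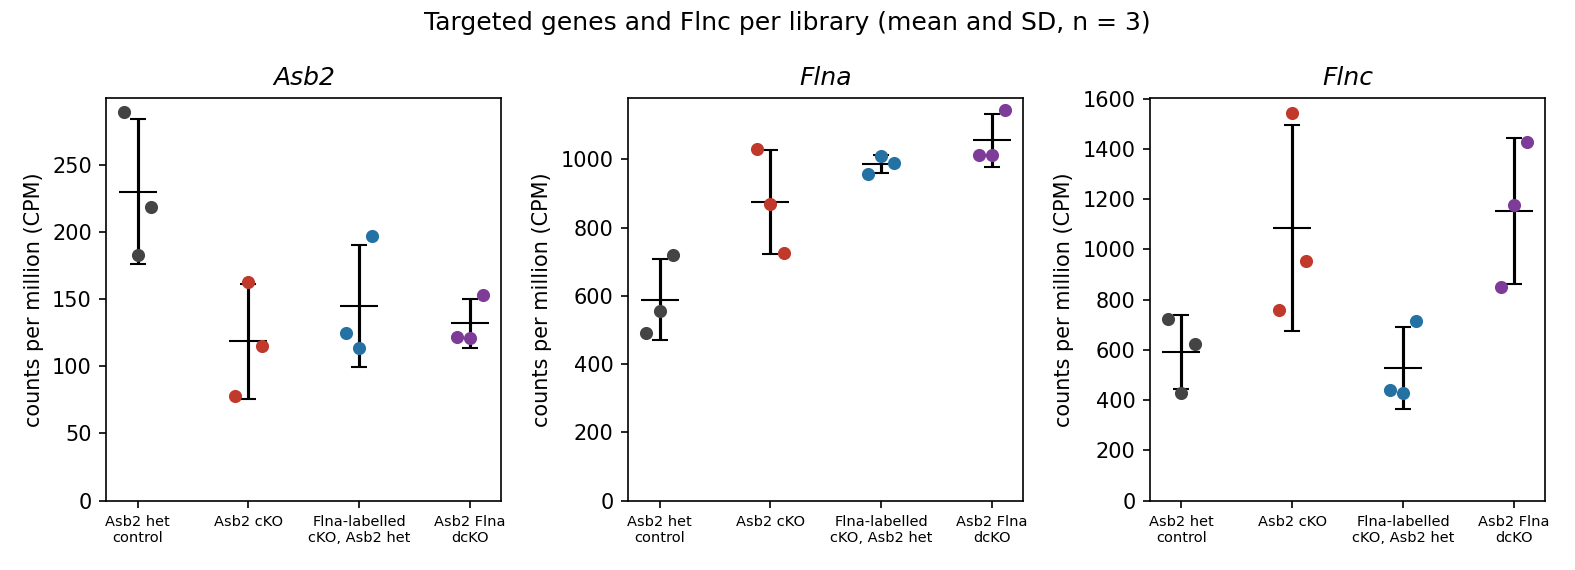
Levels of the targeted genes Asb2 and Flna and of the muscle filamin gene Flnc, in CPM on linear axes. Each point is 1 of the 12 libraries, and bars give the mean and SD of the 3 libraries of each genotype group. The 6 libraries labelled as carrying floxed Flna sit between 958 and 1146 CPM of Flna, and the control libraries between 490.3 and 721 CPM.

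In the Asb2 cKO many genes of low oxygen and glycolysis and of the amino acid stress response rose, and many genes of primitive red blood cells and of mitochondrial respiration fell. As lists these passed with a preset correlation between genes and did not with an estimated one (adjusted p from 0.547 to 0.764). In the Asb2 cKO against the control, with 3 libraries each, Ndufa4l2, a hypoxia-induced mitochondrial protein, rose from 2.5 ± 0.667 to 66.9 ± 13.7 CPM (log2 fold change 4.49, SE 0.23, adjusted p = 2.67e-06). Ddit4, a stress-induced inhibitor of mTOR, rose from 30.6 ± 4.88 to 375 ± 67.4 CPM (log2 fold change 3.59, SE 0.17, adjusted p = 2.42e-06). Chac1, which degrades glutathione during the unfolded protein response, rose from 0.637 ± 0.273 to 21.5 ± 9.63 CPM (log2 fold change 4.21, SE 0.34, adjusted p = 8.36e-05). The embryonic beta-globin Hbb-y fell from 4093 ± 412 to 382 ± 171 CPM (log2 fold change -3.51, SE 0.27, adjusted p = 9.25e-05). Stmn4, a tubulin-binding stathmin of neurons, had the largest rise under the naming rule, from 3.15 ± 2.24 to 87.5 ± 24.2 CPM (log2 fold change 4.79, SE 0.47, adjusted p = 0.000574).

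Of the 35 measured genes of hypoxia and glycolysis, 32 rose and 0 fell, and 33 rose and 1 fell when adjusted over the list alone. The median log2 fold change of this list was 1.48 (camera with preset correlation, adjusted p = 1.42e-19, and adjusted p = 0.547 with an estimated correlation). Its members included Egln3, an oxygen-sensing prolyl hydroxylase (3.19, SE 0.23, adjusted p = 4.79e-05), and Ndrg1 (3.93, SE 0.19, adjusted p = 2.42e-06). The glycolytic enzyme gene Eno2, outside the list, rose from 6.22 ± 1.62 to 123 ± 51.6 CPM (4.14, adjusted p = 4.79e-05). Of 26 genes of the integrated stress response and amino acid synthesis, 20 rose and 0 fell (22 and 0 adjusted over the list alone). The median was 1.27 (adjusted p = 1.41e-13, and adjusted p = 0.614 with an estimated correlation). Shmt2, the mitochondrial serine hydroxymethyltransferase, rose from 92.8 ± 3.79 to 232 ± 24.1 CPM (1.31, adjusted p = 0.000209). The cationic amino acid transporter gene Slc7a3, outside the list, rose from 1.87 ± 0.172 to 32.5 ± 17 CPM (3.68, adjusted p = 0.000103). In the same comparison hemoglobin transcripts took 0.051 to 0.117% of the signal in the Asb2 cKO libraries and 0.708 to 0.782% in the control. Of 23 primitive erythroid markers, 20 fell and 0 rose (22 and 0 adjusted over the list alone). The median was -2.83 (adjusted p = 7.67e-18, and adjusted p = 0.547 with an estimated correlation). They included Klf1, the erythroid master transcription factor (-3.18, SE 0.34, adjusted p = 0.000292), and Hemgn (-3.99, SE 0.38, adjusted p = 0.000209). Reads of the near-identical globin genes could be split between copies, so single globin values are uncertain.

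Of 52 genes of oxidative phosphorylation and mitochondria, 29 fell and 1 rose (35 and 1 adjusted over the list alone). The median was -0.59 (adjusted p = 8.03e-11, and adjusted p = 0.764 with an estimated correlation). Fold changes correlated with gene length at 0.25, and of 7 genes of the mitochondrial genome 6 fell (median -0.93). With trends over gene length and GC content removed, the list was at -0.44 and passed. Against the same control libraries, genes of the mitochondrial genome were also lower in the libraries labelled Flna-deleted (median -1.04). The fall is thus not particular to the Asb2 cKO, and a part of it may come from the shared controls. Idh3a, of the citric acid cycle, fell from 322 ± 19.2 to 158 ± 16.2 CPM (-1.03, adjusted p = 0.000778). Atp5g1, a subunit of ATP synthase, fell from 122 ± 16 to 56.3 ± 9.45 CPM (-1.12, adjusted p = 0.00121). Of 42 cell cycle genes, 8 fell and 0 rose (6 and 0 adjusted over the list alone). The median was -0.27 (adjusted p = 0.00208, and adjusted p = 0.784 with an estimated correlation), E2f2 among them (-1.29, SE 0.21, adjusted p = 0.00302). The level of the cell cycle list in Asb2 cKO library 1, as a median log2 deviation, was 0.108, within the control range of 0.097 to 0.215, and without Asb2 cKO library 2 the median was -0.15 (adjusted p = 0.0419). Of 48 genes of TGF-beta and BMP signalling, 13 rose and 1 fell over all genes and adjusted over the list alone. The median was 0.27 (adjusted p = 0.00595, and adjusted p = 0.764 with an estimated correlation). Ctgf, a matricellular growth factor, rose from 51.7 ± 5 to 212 ± 67.2 CPM (1.98, adjusted p = 0.000455). Of 27 genes of the second heart field and outflow tract, 4 rose and 0 fell on both adjustments. The median was 0.49 (adjusted p = 0.00484, and adjusted p = 0.784 with an estimated correlation). That call was lost without control library 1 (0.14, adjusted p = 0.199) and the median was 0.87 without control library 2, within 2.8e-05 to 0.199 over 20 alternatives. Markers of pharyngeal endoderm and ectoderm, tissues next to the heart, were also higher, with 10 of 24 up and 1 down (16 and 1 adjusted over the list alone) and a median of 1.02 (adjusted p = 1.23e-06, and adjusted p = 0.764 with an estimated correlation).

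The sarcomere list did not pass in the Asb2 cKO, where its libraries stood apart. Of 35 sarcomere genes, 3 rose and 3 fell on both adjustments. The median was -0.00 (adjusted p = 0.890), while the list was at a median log2 deviation of -0.407, 0.316 and 0.291 in the 3 Asb2 cKO libraries and 0.442, -0.146 and 0.011 in the control. Its members were correlated over the libraries, at an estimated 0.727. Lmod2, which elongates actin filaments, rose from 48.4 ± 3.41 to 109.6 ± 24.6 CPM (1.15, adjusted p = 0.00187). Xirp2, a protein of intercalated discs, rose from 0.385 ± 0.467 to 4.65 ± 1.27 CPM (2.63, adjusted p = 0.00234). Of 28 genes of calcium handling and ion channels, 6 fell and 0 rose on both adjustments, while the list did not pass (median 0.02, adjusted p = 0.55). Pln, which inhibits the calcium pump of the sarcoplasmic reticulum, fell from 142 ± 39.5 to 28.8 ± 9.65 CPM (-2.30, adjusted p = 0.000892). The calcium store protein Casq2 fell from 9.85 ± 0.571 to 1.71 ± 0.585 CPM (-2.26, adjusted p = 0.000611). Cav3, a muscle caveolin, fell from 25.8 ± 8.25 to 2.38 ± 0.243 CPM (-3.14, adjusted p = 0.000103). Flnc, the muscle filamin, rose from 591 ± 149 to 1085 ± 409 CPM (0.84, SE 0.27, adjusted p = 0.0467), a call that was lost without control library 2 (0.63, adjusted p = 0.145) or 3 (0.90, adjusted p = 0.0863) and without Asb2 cKO library 2 (0.56, adjusted p = 0.116) or 3 (0.90, adjusted p = 0.0873), within 0.00173 to 0.145 over 21 alternatives. Transcription factor genes of the heart went both ways, with 3 of 30 up and 3 down on both adjustments (median 0.04, adjusted p = 0.926), Hand1 among those that fell (-1.05, SE 0.14, adjusted p = 0.00116).

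In all, 3033 of 14034 genes tested passed in the Asb2 cKO (21.6%), 1505 higher and 1528 lower, and 590 of the former and 340 of the latter changed at least 2-fold. The 2 groups did not overlap for 41.4% of genes, where chance gives 10%. Here and below, that 10% is the average over the splits of the 6 libraries of a comparison. For genes that vary together, a single split can lie far from this average. Of 27 lists tested 8 passed, and the other 19 had adjusted p from 0.0689 to 0.926, 7 of which gave a median, mean and test that differed in sign. The count was 1782 without control library 1, 1580 without control library 2 and 2009 without Asb2 cKO library 2.

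The libraries labelled Flna-deleted, in which Flna itself was not lower, had less hemoglobin transcript and more transcript of a few liver genes than the control. Of 23 primitive erythroid markers, 5 fell and 0 rose (16 and 0 adjusted over the list alone). The median was -0.85 (camera, adjusted p = 2.85e-16, and adjusted p = 0.759 with an estimated correlation). Hbb-y fell from 4093 ± 412 to 1752 ± 239.8 CPM with 3 libraries each (log2 fold change -1.23, SE 0.13, adjusted p = 0.0223), and hemoglobin took 0.304 to 0.411% of the signal against 0.708 to 0.782% in the control. Cebpa, a transcription factor of liver and other tissues, rose from 0.561 ± 0.302 to 7.61 ± 2.55 CPM (log2 fold change 2.93, SE 0.34, adjusted p = 0.0223). Itih2, a liver-secreted matrix protein gene, rose from 0.342 ± 0.479 to 40.8 ± 25.9 CPM (log2 fold change 5.57, SE 0.53, adjusted p = 0.0223). Vtn, which encodes vitronectin, rose from 0.327 ± 0.378 to 13.4 ± 7.52 CPM (log2 fold change 4.05, SE 0.44, adjusted p = 0.0223). Without control library 1, 2 or 3 the adjusted p was 0.0722, 0.0938 and 0.0534 for Hbb-y and for Cebpa, 0.086, 0.14 and 0.0531 for Itih2 and 0.0722, 0.0583 and 0.0911 for Vtn. Without library 1 of the labelled group it was 0.1 for Hbb-y, 0.0586 for Cebpa and 0.0521 for Vtn, and without its library 2 it was 0.0893 for Cebpa, with highest values over all alternatives of 0.277, 0.149, 0.266 and 0.264 for Hbb-y, Cebpa, Itih2 and Vtn.

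These were 3 of the 4 genes that rose (the fourth was Alb, with 4 reads in the control), and the 6 that fell were Hbb-y, Hba-a2, Hbb-bh1, Hba-x, Car2 and Tmem37. In the list of liver bud and yolk sac endoderm markers, 1 of 21 members rose and 0 fell on both adjustments, and the list did not pass (median -0.20, adjusted p = 0.886). Of 51 genes of oxidative phosphorylation, 0 passed over all genes by limma and 31 were lower when adjusted over the list alone. The median was -0.36 (adjusted p = 1.05e-16, and adjusted p = 0.821 with an estimated correlation), Cox6c among those with the smallest p (-0.54, SE 0.12, adjusted p = 0.254). Fold changes in this comparison correlated with gene length at 0.298, and the 7 genes tested of the mitochondrial genome were lower as well, with a median of -1.04. With trends over gene length and GC content removed, the median of the oxidative phosphorylation list was -0.29, and the list passed. The sarcomere list stood lower, with a median of -0.51 over 34 genes (adjusted p = 6.77e-11, and adjusted p = 0.821 with an estimated correlation), but 0 members passed on either adjustment, and Tnni3, cardiac troponin I, was at 349 ± 81.9 against 602 ± 122 CPM (-0.80, adjusted p = 0.292). The sarcomere list was at a median log2 deviation of -0.547, -0.776 and 0.088 in the 3 labelled libraries and 0.442, -0.146 and 0.011 in the control, so that labelled library 3 lay above 2 control libraries. The median was -0.32 without labelled library 2 and -0.77 without labelled library 3. The list of calcium handling genes (median -0.28, adjusted p = 0.0139) was lower, and that of Wnt signalling (0.27, adjusted p = 0.00179) higher. Markers of endocardium and endothelium (-0.25, adjusted p = 0.00414) were lower and those of neural crest (0.57, adjusted p = 0.00179) higher. These 4 lists had 0 members past the threshold over all genes by limma, and 1 down, 3 up, 0 and 1 up in that order adjusted over the list alone, and each had adjusted p from 0.821 to 0.825 with an estimated correlation. The call of the calcium list was lost without control library 3 (-0.22, adjusted p = 0.327) or library 2 of the labelled group (-0.15, adjusted p = 0.256). The Wnt (0.10), endocardium (-0.16) and neural crest (0.23) calls were lost without control library 1, each with adjusted p = 0.0515. Without other libraries the medians moved by over 1.5 times, to -0.18 (control library 1) and -0.52 (labelled library 3) for calcium handling and -0.16 (labelled library 2) for endocardium. For neural crest they were 1.00 without control library 2, 0.29 without labelled library 1 and 0.97 without labelled library 3. The hypoxia list did not pass (median -0.03 over 34 genes, 1 up adjusted over the list alone, adjusted p = 0.694).

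The count of 10 genes among 13891 (4 higher, 6 lower) stood beside 1822 genes at an unadjusted p under 0.05, 2 genes called by edgeR and 244 by DESeq2 on the recovered reads, and 117 in the authors' deposited table. Groups did not overlap for 18% of genes, where chance gives 10% on average over splits, and whether 18% exceeds other splits was not tested. The count of genes was 1, 1 and 0 without control library 1, 2 or 3, and 3 and 98 without library 1 or 3 of the labelled group, and none of the 10 genes passed under every alternative. Of 27 lists 7 passed, and 1 of the other 20, with adjusted p from 0.0638 to 0.886, differed in sign between median, mean and test.

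The double mutant, whose Flna transcript was not lower than in the control, had many hypoxia and stress response genes higher and many erythroid and cell cycle genes lower than the control. As lists these passed with a preset correlation and did not with an estimated one (adjusted p from 0.415 to 0.482). With 3 libraries each, Egln3 rose from 10.1 ± 1.25 to 109 ± 11.4 CPM (log2 fold change 3.37, SE 0.14, adjusted p = 6.44e-07). The stress-induced pseudokinase gene Trib3 rose from 4.5 ± 1.34 to 98.4 ± 28.8 CPM (log2 fold change 4.31, SE 0.25, adjusted p = 8.74e-06). Hba-x, the embryonic alpha-like globin, fell from 1855 ± 109 to 119 ± 19.5 CPM (log2 fold change -3.97, SE 0.14, adjusted p = 3.28e-07). Rrm2, a subunit of ribonucleotide reductase, fell from 263 ± 9.65 to 105 ± 9.08 CPM (log2 fold change -1.32, SE 0.10, adjusted p = 2.84e-05).

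Of 35 hypoxia and glycolysis genes, 32 rose and 1 fell in the double mutant (33 and 1 adjusted over the list alone; median 1.65, camera adjusted p = 8.52e-20, and adjusted p = 0.415 with an estimated correlation). P4ha2, a collagen prolyl hydroxylase, rose from 47.5 ± 1.79 to 323 ± 11.7 CPM (2.75, adjusted p = 3.28e-07). Of 26 genes of the integrated stress response, 24 rose and 0 fell (26 and 0 adjusted over the list alone). The median was 1.68 (adjusted p = 7.43e-16, and adjusted p = 0.482 with an estimated correlation). Vldlr, a lipoprotein receptor, rose from 18 ± 3.3 to 193 ± 7.75 CPM (3.41, adjusted p = 6.44e-07). The stress transcription factor Ddit3 rose from 6.78 ± 0.255 to 37.3 ± 3.74 CPM (2.37, adjusted p = 5.51e-06). Hemoglobin took 0.033 to 0.06% of the signal here. Of 23 erythroid markers 21 fell and 0 rose on both adjustments (median -3.39, adjusted p = 1.39e-16, and adjusted p = 0.415 with an estimated correlation). Liver bud and yolk sac markers were lower, with 4 of 17 down and 1 up (9 and 1 adjusted over the list alone; median -2.31, adjusted p = 0.00424, and adjusted p = 0.845 with an estimated correlation). That fall rests on control libraries 1 and 3, at a median log2 deviation of 2.39 and 1.67, while control library 2, at -1.12, lay within the double mutant range of -1.40 to -1.002. The call was lost with a filter of 5 CPM (-3.15, adjusted p = 0.195). Of 42 cell cycle genes, 26 fell and 0 rose (29 and 0 adjusted over the list alone). The median was -0.44 (adjusted p = 8.21e-08, and adjusted p = 0.482 with an estimated correlation). Ccne1, the G1/S cyclin E1, fell from 76.1 ± 4.55 to 25.7 ± 2.4 CPM (-1.55, adjusted p = 2.47e-05). Of 52 genes of oxidative phosphorylation, 31 fell and 3 rose (33 and 3 adjusted over the list alone; median -0.50, adjusted p = 2.01e-07, and adjusted p = 0.576 with an estimated correlation). Fold changes correlated with gene length at 0.246, of 8 genes of the mitochondrial genome 7 fell and 1 rose (median -1.35), and with trends over length and GC content removed the list was at -0.39 and passed.

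Of 48 TGF-beta and BMP genes, 19 rose and 2 fell (20 and 2 adjusted over the list alone; median 0.34, adjusted p = 0.00166, and adjusted p = 0.576 with an estimated correlation), and Ctgf rose from 51.7 ± 5 to 281 ± 38 CPM (2.43, adjusted p = 2.2e-06). Of 30 markers of endocardium and endothelium, 12 rose and 2 fell on both adjustments (median 0.35, adjusted p = 0.0224, and adjusted p = 0.767 with an estimated correlation). Flt1, a VEGF receptor, rose from 61.4 ± 7.92 to 182 ± 14.7 CPM (1.57, adjusted p = 2.75e-05). Sox17 rose from 5.82 ± 1.29 to 24.1 ± 2.68 CPM (1.97, adjusted p = 9.88e-05). The endocardium call was lost without double mutant library 3 (0.25, adjusted p = 0.0885). Of 20 Notch genes 7 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.40, adjusted p = 0.0436, and adjusted p = 0.576 with an estimated correlation). Of 24 genes of the p53 pathway 11 rose and 3 fell on both adjustments (median 0.46, adjusted p = 0.0447, and adjusted p = 0.482 with an estimated correlation). Of 17 neural crest markers 4 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.65, adjusted p = 0.0436, and adjusted p = 0.767 with an estimated correlation). The Notch list was lost without control library 1 (0.25, adjusted p = 0.0693) and without double mutant library 1 (0.32, adjusted p = 0.0701) or 2 (0.45, adjusted p = 0.0574). The p53 list was lost without double mutant library 2 (0.46, adjusted p = 0.0574), and the neural crest list without control library 1 (0.45, adjusted p = 0.134) or double mutant library 1 (0.53, adjusted p = 0.144) or 2 (0.71, adjusted p = 0.0526). Over 20 alternatives the adjusted p ran from 0.00363 to 0.316 for endocardium, 0.00427 to 0.0701 for Notch, 0.022 to 0.067 for p53 and 0.00135 to 0.144 for neural crest. The calls were lost in 2, 6, 5 and 7 of these alternatives in that order, of which the losses named above are a part. Of 36 sarcomere genes 5 rose and 3 fell on both adjustments (median 0.12, adjusted p = 0.509), Lmod2 among those that rose (1.44, SE 0.13, adjusted p = 7.26e-05). Flnc rose from 591 ± 149 to 1152 ± 289 CPM (0.96, adjusted p = 0.0129). That call was lost, among other alternatives, without double mutant library 2 (0.93, adjusted p = 0.0505, within 3.3e-05 to 0.327 over 21 alternatives).

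In total 4523 of 14015 genes passed in the double mutant (32.3%), 2182 higher and 2341 lower, with 670 and 376 changed at least 2-fold and groups apart for 47.8% of genes, where chance gives 10%. Of 27 lists 11 passed, and of the other 16, with adjusted p from 0.0595 to 0.842, 5 differed in sign between median, mean and test. Without double mutant library 2 the count was 2883.

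**Figure D2:**
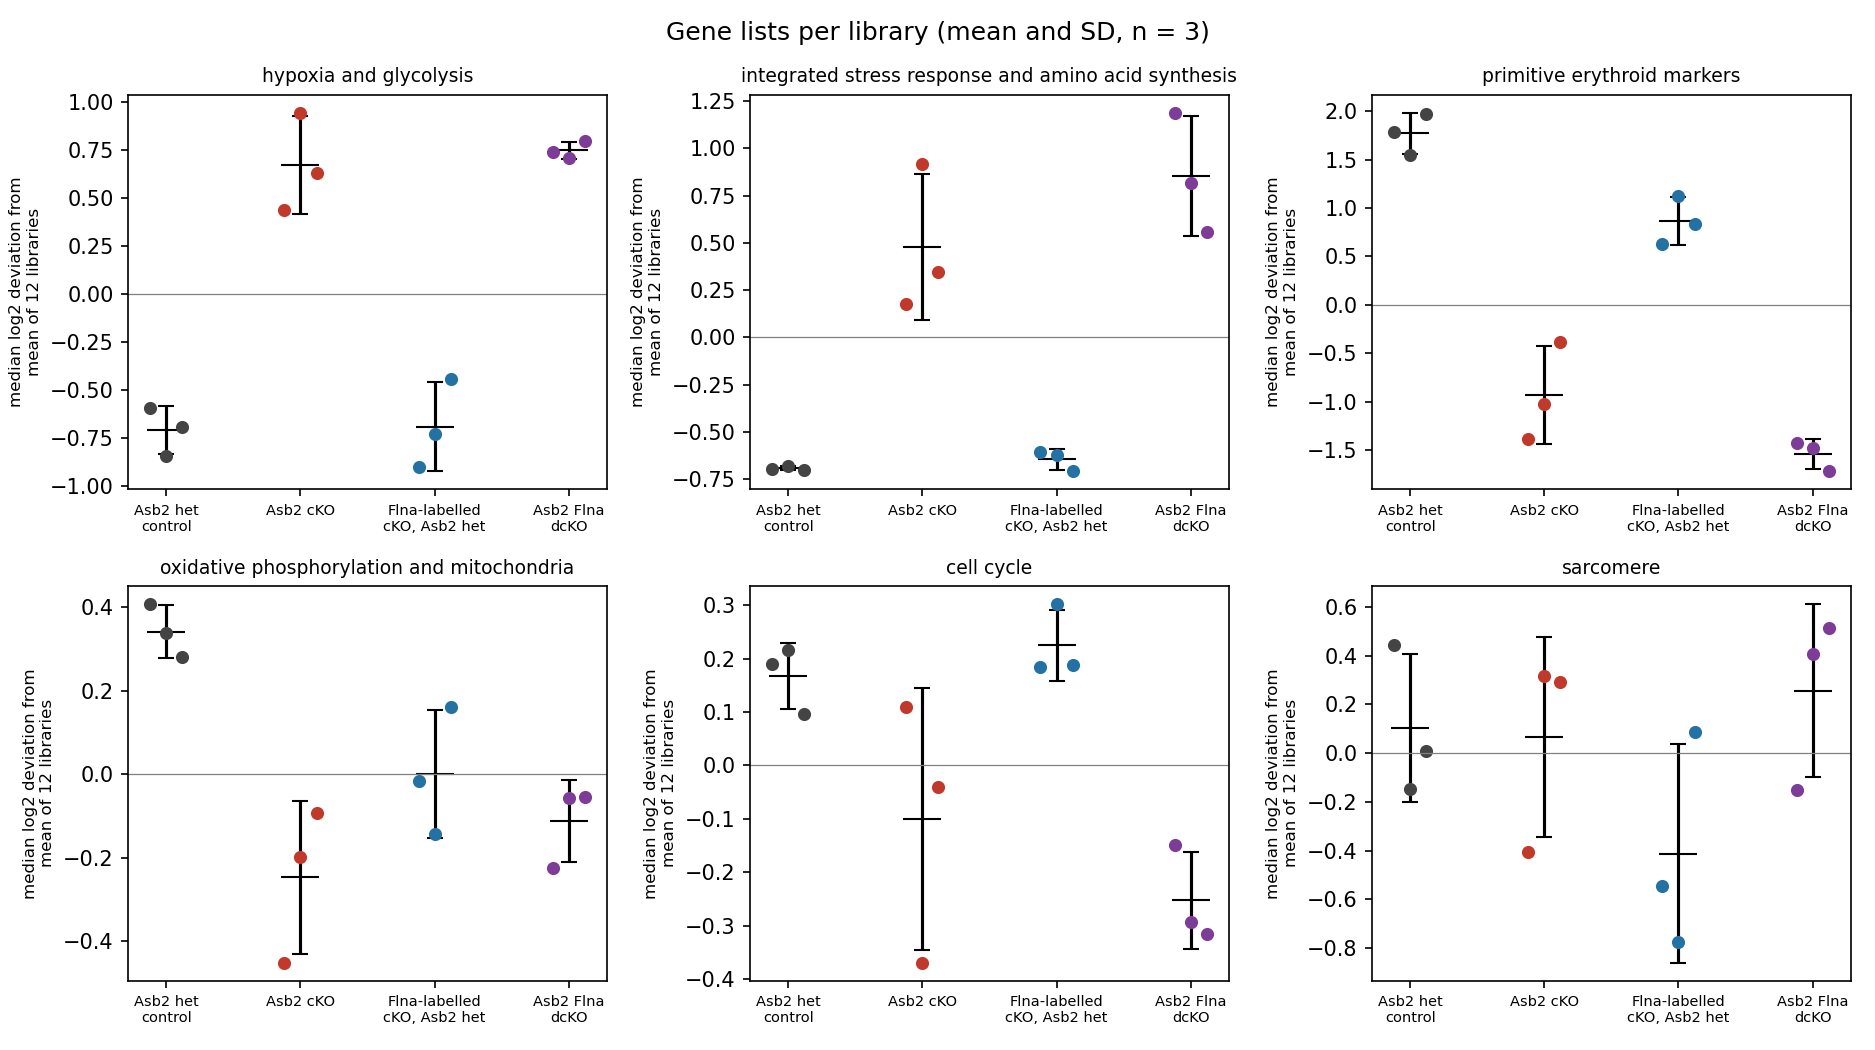
Levels of 6 fixed gene lists in each of the 12 libraries, as the median over the members of the log2 deviation from the mean of all libraries, on linear axes. Each point is 1 library, and bars give the mean and SD of the 3 libraries of each genotype group. The hypoxia and glycolysis list lies between -0.84 and -0.59 in the control libraries, 0.44 and 0.94 in the Asb2 cKO, -0.91 and -0.44 in the libraries labelled Flna-deleted, and 0.71 and 0.80 in the double mutant.

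Set directly against the Asb2 cKO, the double mutant differed in few genes. Gm10260 (chromosome 13, 97760072 to 97760632, minus strand), annotated as protein-coding, rose from 3.09 ± 1.23 to 121 ± 45.9 CPM with 3 libraries each (log2 fold change 5.05, SE 0.32, adjusted p = 0.000239). Gm11942 (chromosome 4, 32964888 to 32965232, plus strand), a processed pseudogene, rose from 1.46 ± 0.383 to 19.2 ± 1.2 CPM (log2 fold change 3.34, SE 0.22, adjusted p = 0.000239). Gm13394 (chromosome 2, 28933610 to 28934609, minus strand), another processed pseudogene, fell from 406 ± 50.9 to 161 ± 21.4 CPM (log2 fold change -1.34, SE 0.15, adjusted p = 0.0185). Genes of this kind can share reads with near-identical copies, so their values are uncertain.

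The next smallest p-values did not pass. The mitochondrial mt-Nd3 had 0 reads in the Asb2 cKO libraries and 2.27 ± 0.316 CPM in the double mutant, at least 61.9-fold above a floor of 3 reads over the group (adjusted p = 0.0703). Pyy, a gut peptide gene, was at 1.08 ± 0.449 against 6.25 ± 2.09 CPM (-2.08, adjusted p = 0.27). In a joint fit of the 4 groups the calls of Gm10260, Gm11942 and Gm13394 were all lost (adjusted p = 0.998 for each), and in the joint fit without libraries with Xist too (adjusted p = 0.496, 0.472 and 0.938). The call of Gm13394 was also lost by limma without trend or robust (adjusted p = 0.188), with Xist as a covariate (-1.14, adjusted p = 0.265), without Asb2 cKO library 1 (-1.28, adjusted p = 0.108) or 3 (-1.28, adjusted p = 0.31) and without double mutant library 1 (-1.22, adjusted p = 0.0612), 2 (-1.39, adjusted p = 0.15) or 3 (-1.40, adjusted p = 0.0585), within 1.06e-14 to 0.998 over 21 alternatives. Of 27 gene lists 11 passed with the preset correlation, 6 higher and 5 lower, with adjusted p from 0.639 to 0.82 with an estimated correlation and 0 members past the threshold by limma over all genes. Genes of the integrated stress response stood 0.35 higher at the median (adjusted p = 2.6e-07), with Asns at 218 ± 57.1 against 151 ± 38 CPM, and endocardium markers 0.23 higher (adjusted p = 5.26e-05). Immediate early and heat shock genes were 0.18 higher (adjusted p = 0.00195), sarcomere genes 0.15 (adjusted p = 0.00601), chamber genes 0.14 (adjusted p = 0.033) and oxidative phosphorylation genes 0.10 (adjusted p = 0.00226). Erythroid markers stood at a median of -0.63 (adjusted p = 2.66e-07), liver markers at -0.93 (adjusted p = 0.000104, but 0.0062 with a filter of 5 CPM, adjusted p = 0.749, and with Asb2 cKO library 2 within the double mutant range) and pharyngeal markers at -0.46 (adjusted p = 1.86e-05, 2 down adjusted over the list alone). Second heart field genes were at -0.20 (adjusted p = 0.000172) and cell cycle genes at -0.13 (adjusted p = 0.000164). In the other 10 called lists 0 members passed when adjusted over the list alone. In a joint fit without the libraries with Xist, the medians were reversed for sarcomere (-0.15), chamber (-0.089), endocardium (-0.14), cell cycle (0.15), second heart field (0.093) and pharyngeal (0.30) genes. Of the 11 lists, erythroid markers alone kept direction and call there (-0.35, adjusted p = 0.00892). With Xist as a covariate, the median of cell cycle genes was 0.020, and that of stress response genes 0.0098 with the direction of camera reversed, and neither passed.

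Of those lists, 7 lost the call without Asb2 cKO library 1, where medians were -0.08 for sarcomere, 0.05 for chamber, -0.03 for cell cycle, 0.02 for oxidative phosphorylation, 0.12 for immediate early genes, 0.12 for endocardium and -0.11 for second heart field genes. Without double mutant library 3 the medians of sarcomere (0.06), chamber (0.09), oxidative phosphorylation (0.07), immediate early (0.14), endocardium (0.18), second heart field (-0.07) and pharyngeal (-0.05) genes did not pass, and without its library 2 that of sarcomere genes (0.07). Medians that passed but moved by over 1.5 times included 0.22, 0.56 and 0.18 for the stress response without Asb2 cKO library 1 or 2 or double mutant library 1, -0.31 for erythroid markers without Asb2 cKO library 3, and -0.37 for liver and -0.18 for pharyngeal markers without Asb2 cKO library 1. This is a part of such moves, and the sarcomere median also rose by over 1.5 times with a library left out. The 3 genes among 14037 stood beside 471 at an unadjusted p under 0.05, 4 by edgeR, 14 by DESeq2 and 22 in the authors' deposited table, with 26 without Asb2 cKO library 2 and groups apart for 7.9% of genes, where chance gives 10%. Lists that did not pass had adjusted p from 0.0508 to 0.897, and 4 of these 16 differed in sign between median, mean and test.

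The double mutant was also set against the libraries labelled Flna-deleted, a comparison added after the values were seen. It is a contrast in the number of floxed Asb2 alleles between groups that share the Flna label, in neither of which Flna was low. The difference in Asb2 transcript itself did not pass (-0.10, SE 0.21, adjusted p = 0.737), so the contrast rests on the labels. Vegfa, the vascular growth factor, rose from 59.2 ± 9.81 to 297 ± 4.9 CPM with 3 libraries each (log2 fold change 2.33, SE 0.12, adjusted p = 2.32e-05). Ndufa4l2 rose from 1.8 ± 0.359 to 76.8 ± 8.28 CPM (log2 fold change 5.08, SE 0.17, adjusted p = 1.58e-06). Nppb, a natriuretic peptide of working myocardium, rose from 53.1 ± 20.5 to 209.7 ± 31.1 CPM (log2 fold change 2.03, SE 0.24, adjusted p = 0.00119). Cdc6, which licenses replication origins, fell from 60.6 ± 4.34 to 26.9 ± 3.01 CPM (log2 fold change -1.16, SE 0.11, adjusted p = 0.000355). Afp, the fetal liver and yolk sac protein, fell from 199.8 ± 150.2 to 0.43 ± 0.372 CPM (log2 fold change -7.59, SE 0.54, adjusted p = 0.000187). Within the control and within the Asb2 cKO, Afp also varied widely, with a library of each far below the others, as given at the end.

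Of 35 hypoxia and glycolysis genes 33 rose and 0 fell (34 and 0 adjusted over the list alone; median 1.43, adjusted p = 7.36e-20, and adjusted p = 0.421 with an estimated correlation), and of 25 stress response genes 22 rose and 0 fell (23 and 0; median 1.44, adjusted p = 2.59e-15, and adjusted p = 0.421 with an estimated correlation). Cell cycle genes fell in 33 of 42 cases with 0 up (34 and 0 adjusted over the list alone; median -0.48, adjusted p = 5.79e-10, and adjusted p = 0.421 with an estimated correlation). Of 34 sarcomere genes 13 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.67, adjusted p = 4.11e-05, and adjusted p = 0.842 with an estimated correlation). The libraries overlapped, with labelled library 3 at 0.088 above double mutant library 1 at -0.149, and the median was 0.43 with Xist as a covariate. Tcap, the titin cap, rose from 34.1 ± 8.01 to 122 ± 24.6 CPM (1.83, adjusted p = 0.000571). Csrp3, a muscle LIM protein, rose from 393 ± 135 to 856 ± 151 CPM (1.16, adjusted p = 0.00943). Endocardium markers (14 up and 1 down of 30, 15 and 1 adjusted over the list alone; median 0.48, adjusted p = 3e-05, and adjusted p = 0.56 with an estimated correlation) and actin cytoskeleton genes (18 up and 2 down of 44, 19 and 3 adjusted over the list alone; median 0.30, adjusted p = 0.00342, and adjusted p = 0.781 with an estimated correlation) were higher. Immediate early and heat shock genes went both ways, with 11 of 18 up and 4 down on both adjustments (median 0.68, adjusted p = 0.0121, and adjusted p = 0.421 with an estimated correlation). Among them Ier3 rose (3.22, SE 0.19, adjusted p = 4.16e-05) and the chaperone gene Hsph1 fell (-1.62, SE 0.12, adjusted p = 9.63e-05). Of 49 TGF-beta genes 15 rose and 2 fell on both adjustments (median 0.31, adjusted p = 0.00362, and adjusted p = 0.55 with an estimated correlation), and of 24 p53 genes 8 rose and 3 fell (11 and 3 adjusted over the list alone; median 0.29, adjusted p = 0.0121, and adjusted p = 0.421 with an estimated correlation). Of 20 Notch genes 4 rose and 1 fell (5 and 2 adjusted over the list alone; median 0.26, adjusted p = 0.0486, and adjusted p = 0.655 with an estimated correlation). The Notch call was lost without library 2 (0.25, adjusted p = 0.0597) or 3 (0.23, adjusted p = 0.0902) of the labelled group and without double mutant library 1 (0.20, adjusted p = 0.138), within 0.0155 to 0.138 over 20 alternatives. Hemoglobin took 0.033 to 0.06% of the signal against 0.304 to 0.411%, and of 23 erythroid markers 20 fell and 0 rose on both adjustments (median -2.52, adjusted p = 5.48e-13, and adjusted p = 0.294 with an estimated correlation). Of 16 liver markers 10 fell and 1 rose (10 and 2 adjusted over the list alone; median -2.25, with the 2 members at 0 in the double mutant set to their bound also -2.25, adjusted p = 0.000284, and adjusted p = 0.56 with an estimated correlation), a call lost with a filter of 5 CPM (-4.48, adjusted p = 0.251).

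This comparison called 4394 of 13954 genes (31.5%), 2113 higher and 2281 lower, so that 48.1% were higher. Scaling to the total without the hemoglobin genes gave 1695 higher and 2814 lower, or 37.6% higher. That scaling also replaced the deposited library sizes, with column sums of 942334 to 1009593 in the labelled group and 988716 to 1051801 in the double mutant. Hemoglobin took at most 0.411% of reads in these libraries, too little for its removal alone to give that shift. At least 2-fold changes were seen for 613 and 341 genes, and groups were apart for 47.5% of genes, where chance gives 10%. The count was 2801 and 2780 without library 1 or 2 of the labelled group and 2710 without double mutant library 2. Of 27 lists 12 passed, and of the other 15, with adjusted p from 0.111 to 0.898, 5 differed in sign between median, mean and test. The oxidative phosphorylation list was among those that did not pass here.

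Genes changed in the Asb2 cKO kept nearly the same fold change in the double mutant, in which Flna was not low. Of the 3033 genes called in the Asb2 cKO, 2611 were called in the same direction in the double mutant against the same control, 1266 higher (Ndrg1 at 3.93 and 3.67) and 1345 lower (Casq2 at -2.26 and -2.20), and 0 genes were called in opposite directions by limma. Independent lists of these sizes would share 232 and 257 of the 13878 genes tested in both. Across genes, which are not independent replicates, the correlation of fold changes was 0.916 and 88.1% had the same sign, against 0.501 and 66.7% in 50 simulations of unchanged groups on the shared controls, which called 0 genes in common. With noise drawn for each gene independently, these simulations could hardly call any gene, so their 0 was nearly fixed in advance. They do not show what variation shared by the genes of a control library would give. The covariance was 0.345 against a simulated 0.0297, a difference of 0.315, and with 3 control libraries that could not be split, part of the excess in shared calls may come from the shared controls. The Asb2 cKO against the control and the double mutant against the libraries labelled Flna-deleted share no library, and there 974 genes rose and 948 fell in both comparisons against 225 and 247 for independent lists, with 4 opposite and a correlation of 0.691. The 2611 shared calls were 1604 without control library 1, 1385 without control library 2 and 1699 without Asb2 cKO library 2.

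Turned so that the direction in the Asb2 cKO is positive, the 3033 genes had a median log2 fold change of 0.78 in the Asb2 cKO, 0.74 in the double mutant and 0.17 in the libraries labelled Flna-deleted, where 8 were called in the same direction. The control libraries used to select the genes enter all these values. A positive value such as 0.17 can arise from them alone, and no simulation was set beside it. Between the double mutant and the Asb2 cKO, 2969 of them were tested, and their median difference was -0.031 (-0.02, -0.07 and 0.01 for the 3 double mutant libraries, SD 0.04), with 57.3% closer to the control. Selecting genes in libraries that enter the difference gave -0.041 (-0.0486 to -0.0329) and 59.8% in 50 simulations with no effect of Flna. These selected 4925 genes on average, more than the 3033 observed, and the observed difference was nearer 0 than in any of them. They drew noise for each gene independently, without variation that the genes of a library share. Their range is therefore too narrow to judge the observed difference, and nothing is concluded from it. By limma 1 of the genes, Gm13394, moved back and 0 moved further, with 90 and 44 at an unadjusted p under 0.05. The median difference was -0.064, -0.000728 and -0.11 without Asb2 cKO library 1, 2 or 3. It was -0.030, -0.0090 and -0.051 without double mutant library 1, 2 or 3, and -0.13 with Xist as a covariate.

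**Figure D3:**
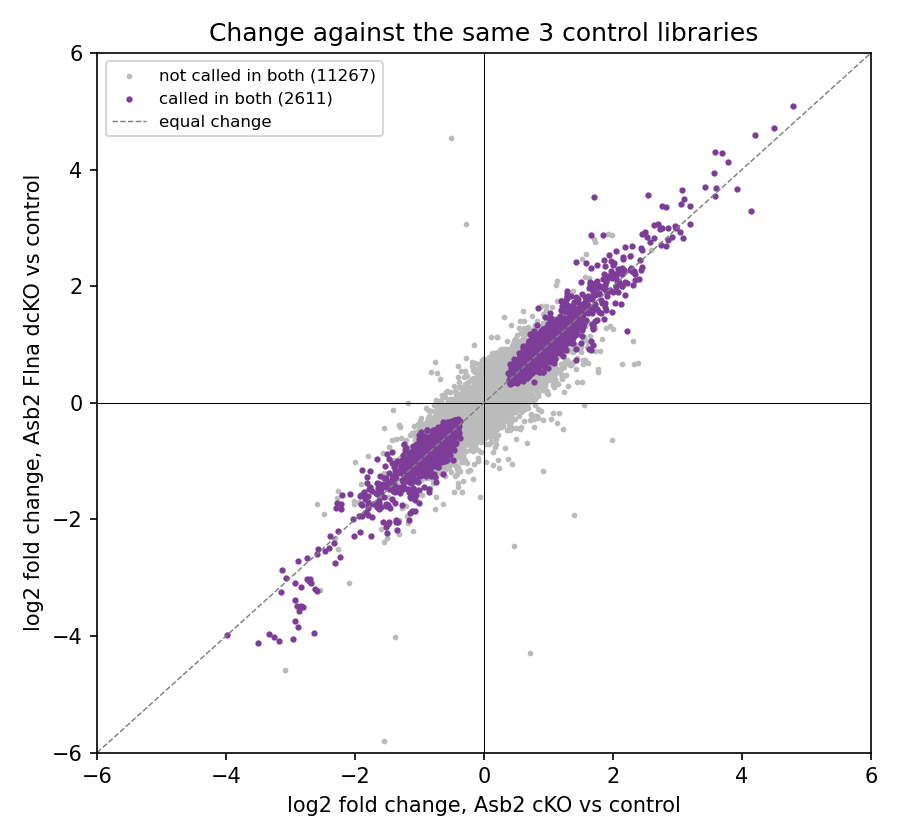
Log2 fold change of each gene in the double mutant against that in the Asb2 cKO, both against the same 3 control libraries, on linear axes. Purple points are the 2611 genes called in both comparisons, grey points the others of the 13878 genes tested in both, and the dashed line marks equal change. The correlation of 0.916 compares with 0.501 in simulations of unchanged groups on the shared controls. These drew noise for each gene independently, without variation that the genes of a library share.

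Whether the difference linked to the Flna label depended on Asb2 was tested as an interaction over all 12 libraries. For Asb2 itself the interaction was 0.89 (log2, SE 0.38, adjusted p = 0.503) and for Flna -0.48 (SE 0.22, adjusted p = 0.504), with Flnc at 0.29 (SE 0.42, adjusted p = 0.822). Of 13981 genes, 0 passed by limma and 0 by edgeR, with a lowest adjusted p of 0.0887 and 1372 genes at an unadjusted p under 0.05. The count was 18 without Asb2 cKO library 2 and 1 without library 2 of the group labelled Flna-deleted.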

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

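All explanations weighed here, and the counts over other splits, were tested only after the result was seen, while the interaction itself was planned. In the interaction over 12 libraries, which sets the double mutant minus the Asb2 cKO against the libraries labelled Flna-deleted minus the control, 13 of 27 gene lists passed camera with the preset correlation. With an estimated correlation their adjusted p ran from 0.507 to 0.707, and by limma 0 genes passed over all genes. Median interactions on the log2 scale were 0.73 for sarcomere genes, 0.43 for calcium handling genes, 0.37 for chamber genes, 0.49 for oxidative phosphorylation genes and 0.45 for endocardium markers. They were 0.31 for the integrated stress response, 0.34 for immediate early and heat shock genes and 0.30 for primitive erythroid markers. Negative medians were found for pharyngeal markers (-0.71), second heart field genes (-0.60), neural crest markers (-0.39), Wnt genes (-0.26) and cell cycle genes (-0.19). The lists of the interaction were not repeated under the alternative settings or with a library left out. How far these medians rest on single libraries is therefore not known, and sarcomere members had an estimated correlation of 0.82. Counts over regroupings of the 12 libraries decide nothing here, since any count is at least the 0 genes of the real grouping by limma (1372 at an unadjusted p under 0.05, 0 by edgeR). Of 100 regroupings 100 reached it, and the highest called 1268, in contrasts that mix in the difference between the Asb2 genotypes.

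In the Asb2 cKO, genes of hypoxia and the integrated stress response were higher while erythroid transcripts were lower. A loss of blood RNA that raised the share of all other RNA would move sarcomere genes by as much as the hypoxia list, and their median was -0.000886 (SD over members 0.703) against 1.48. Hemoglobin took at most 0.782% of control reads, so its loss alone could hardly raise other shares. For hemoglobin the outcome of this comparison was thus fixed in advance. The sarcomere list also varied between libraries (SE of its difference 0.295). Trends over gene length and GC content are also argued against as the whole cause, since the hypoxia median was 1.38 after their removal (adjusted p = 7.89e-19). Hypoxia genes rising in proportion to the loss of erythroid transcripts would give a median of 0.44 in the libraries labelled Flna-deleted, where erythroid markers stood at -0.85, and the median was -0.031 (combined SE 0.18). That SE leaves out the error of the ratio taken from the Asb2 cKO. It also treats values that share the control libraries as independent, so it is not the full error of the gap. An effect of Asb2 deletion, which the design names, stays open as a hypothesis found and tested on the same libraries, and so does a change in the composition or staging of the dissected tissue, which was not tested.

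Gm10260 and Gm11942 were higher in the double mutant than in the Asb2 cKO. If Flna deletion acted alike with and without Asb2, both genes would be high in the 3 libraries labelled Flna-deleted, and 3 of 6 values lay above all libraries without that label. In those libraries Gm10260 was at 129, 3.17 and 99.5 CPM and Gm11942 at 2.02, 40.0 and 0.955 CPM. The highest Gm10260 value was 40.9 times the lowest, as a sequence variant carried by part of the animals could give, and this cannot be told apart from reads shared with near-identical copies, since no genotype beyond the targeted alleles is given. Of the 3 libraries labelled Flna-deleted, which by their labels keep an Asb2 allele, 2 lay above the lowest double mutant value of Gm10260 (68.4 CPM) and 1 above that of Gm11942 (18.1 CPM). Were the labels borne out, the Gm10260 values would go against an effect that needs both deletions, and the mixed values against Flna deletion acting alike. Flna was not low in these libraries and Asb2 did not differ past the threshold between them and the double mutant (-0.10, SE 0.21, adjusted p = 0.737), so both explanations stay open.

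Flna was not lower in the libraries labelled Flna-deleted. With Xist as a covariate, to allow for sex of the embryos, the difference between the double mutant and the control was 1.04 (SE 0.18, adjusted p = 0.00618, within 1.48e-07 to 0.0133 over 21 alternatives). Xist itself differed between these groups, and among the controls it was low in library 1 alone. The adjusted difference therefore rests largely on that library, and sex stays open. An exchange of labels cannot be told apart from other causes, since 5 of the 6 libraries without the label lay below 958 CPM, the lowest labelled value, and the sequence of the alleles was not analysed here. A deletion that leaves most of the transcript could keep counts up, but the value of 0.76 in the libraries labelled Flna-deleted decides nothing without reads per exon. Apart from sex, by the Xist covariate, no biological explanation was tested.

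Splits of 3 against 3 libraries are 10 in number, too few for a share under 0.05. The real split called 3033 genes in the Asb2 cKO against the control and the highest other split 0, with 1 of 10 splits as large. For the libraries labelled Flna-deleted the real split called 10 and the highest other 65, with 2 splits as large. The double mutant against the control gave 4523 and 0, with 1 split as large, and against the Asb2 cKO 3 and 14, with 2 splits as large. Against the libraries labelled Flna-deleted it gave 4394 and 0, with 1 split as large.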

How the results depend on the processing

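The Xist covariate, the removal of length and GC trends, the joint fit without libraries with Xist and the comparison of the double mutant with the libraries labelled Flna-deleted were chosen after the data were seen, and the other alternatives were planned. Over all alternatives the named genes gave 5889 values on the same side of the threshold and in the same direction, 259 no longer past it and 27 newly past it, and the gene lists 2514, 61 and 108, with 15 reversed. With the replicate number as a block, which the correlations of libraries do not favour, 1557 genes passed in the Asb2 cKO against 3033, 1 in the libraries labelled Flna-deleted against 10, and 1426 instead of 2611 were shared with the double mutant. For the libraries labelled Flna-deleted the count was 0 by limma without trend or robust, with 1822 genes at an unadjusted p under 0.05 in the fit as reported, 29 with array weights, 2 by edgeR, 244 by DESeq2, 2 in the joint fit of 4 groups, 0 with the Xist covariate and 0 in the joint fit without libraries with Xist. That last fit leaves the control and the Asb2 cKO 1 library each, assumed to vary like the other groups, and called 2851 genes in the double mutant against the control. For the double mutant against the Asb2 cKO it called 0 genes, the joint fit of all libraries 0 and DESeq2 14. The interaction called 8 genes with array weights and 5 with the Xist covariate, with which the median of the Asb2 cKO genes in the double mutant was -0.13 instead of -0.03. Leaving out 1 library at a time gave 1580 to 2511 genes in the Asb2 cKO, 0 to 98 in the libraries labelled Flna-deleted, 2883 to 4347 in the double mutant against the control, 2 to 26 against the Asb2 cKO and 2710 to 4638 against the libraries labelled Flna-deleted. It gave 1385 to 2341 shared genes, a median of -0.11 to -0.000728 for the Asb2 cKO genes in the double mutant and 0 to 18 genes in the interaction. Lists that reversed were the epicardium markers without control library 1, at -0.54 (-0.54 to 0.26 over libraries left out) in the Asb2 cKO and -0.76 (-0.76 to 0.23) in the double mutant against the control. In the double mutant against the Asb2 cKO, the direction of camera turned with the Xist covariate for cell cycle (median 0.020), hypoxia (-0.12) and stress response genes, the last with a median of 0.0098 still above 0. In the joint fit without libraries with Xist it turned for sarcomere (-0.15), calcium handling (-0.21), second heart field (0.093), chamber (-0.089), cell cycle (0.15), hypoxia (-0.21), endocardium (-0.14) and pharyngeal (0.30) lists, and for the oxidative phosphorylation list with a median of 0.014 still above 0. Without Asb2 cKO library 1 it turned for the sarcomere list (-0.076, and -0.076 to 0.35 over libraries left out). With a filter of 5 CPM the liver list was no longer called in the double mutant against the Asb2 cKO (0.0062, adjusted p = 0.749). Apart from the smaller number of libraries in some of these fits, the cause was not tested. At 25954539 to 42473118 reads, 3 reads over a group set the lowest level that could be told from 0.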

Other observations

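The genes in this part, and their tests, were chosen after their values were seen. H2-K1, a class I histocompatibility gene, rose from 4.23 ± 0.769 to 33.7 ± 10.6 CPM in the Asb2 cKO (log2 fold change 2.82, SE 0.24, adjusted p = 0.000103) and to 30.05 ± 4.72 CPM in the double mutant (2.69, adjusted p = 1.54e-05), with 5.41 ± 0.693 CPM in the libraries labelled Flna-deleted. The class II gene H2-Ab1 rose from 3.93 ± 1.23 to 35.9 ± 10.4 CPM (log2 fold change 3.04, SE 0.27, adjusted p = 0.000129) and to 32.3 ± 3.86 CPM (2.92, adjusted p = 2.6e-05). Tfrc, the transferrin receptor, rose in the Asb2 cKO (0.79, SE 0.15, adjusted p = 0.00587) and in the double mutant (1.00, SE 0.15, adjusted p = 0.00121), and so did the peptide hormone gene Adm2 (3.08, adjusted p = 0.000281 and 3.65, adjusted p = 9.99e-06). The nuclear RNA Malat1 rose from 354 ± 83.4 to 790.4 ± 296 CPM (1.12, adjusted p = 0.0121) and to 751 ± 109 CPM in the double mutant (1.10, adjusted p = 0.00165), and stood at 164 ± 87.6 CPM in the libraries labelled Flna-deleted (-1.20, adjusted p = 0.32).

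Nppa, Nppb and Myh7 rose in the double mutant against the control, Nppa from 1008 ± 78.8 to 1658 ± 464 CPM (0.68, adjusted p = 0.0189), Nppb to 209.7 ± 31.1 CPM (1.11, adjusted p = 0.0253) and Myh7 from 4886 ± 978 to 8834 ± 2231 CPM (0.84, adjusted p = 0.0172). In the Asb2 cKO they were at 1212 ± 571, 195 ± 51.7 and 7559 ± 2927 CPM and did not pass (adjusted p = 0.747, 0.0511 and 0.158). The difference between these groups did not pass for Nppa, Nppb or Myh7 (adjusted p = 0.999 for each). Genes encoded by the mitochondrial genome had a median log2 fold change of -0.93 in the Asb2 cKO, where 6 of 7 fell. In the double mutant the median was -1.35, with 7 of 8 lower and 1 higher. In the libraries labelled Flna-deleted it was -1.04, with 0 of 7 past the threshold by limma. All these comparisons share the control libraries. The double mutant against the libraries labelled Flna-deleted uses none of those controls, and there the median was -0.35, with 2 of 7 called lower by limma.

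Xist, which is transcribed from the inactive X chromosome, stood at 0.823, 302 and 106 CPM in the control libraries, 571, 0.38 and 377 CPM in the Asb2 cKO, 0.051, 0.123 and 0.367 CPM in the libraries labelled Flna-deleted, and 0.048, 0.546 and 9.34 CPM in the double mutant. The Y-linked Ddx3y stood at 58.6, 0 and 51.4 CPM, 19.3, 84.4 and 32.2 CPM, 68.3, 61.9 and 65.9 CPM, and 73.1, 82.3 and 77.2 CPM in the same order. Control library 3 and Asb2 cKO libraries 1 and 3 had both transcripts above 10 CPM. All libraries labelled Flna fl/fl held Ddx3y at 61.9 CPM or more and Xist at 9.34 CPM or less. Of the others, only control library 1 and Asb2 cKO library 2 held Ddx3y with Xist under 1 CPM. Differences between libraries with and without the Flna label therefore cannot be fully told apart from sex. Flna lies on chromosome X, so the homozygous label fl/fl is at odds with this male pattern of transcripts.

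Afp, the fetal liver and yolk sac protein, was at 158, 3.13 and 200 CPM in the control libraries, 69.9, 1.06 and 41.6 CPM in the Asb2 cKO, 93.7, 372 and 134 CPM in the libraries labelled Flna-deleted, and 0, 0.646 and 0.644 CPM in the double mutant. The first 2 principal components of the 12 libraries took 46.5% and 18.4% of the variance.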
